A study of Mus musculus with 24 samples.

How the data were processed

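Bulk RNA-seq libraries were made from blood stem and progenitor populations sorted from the bone marrow of male C57BL/6 mice, 4 young (12 weeks) and 4 aged (107 weeks). Marrow was first enriched for cells carrying CD117, the receptor tyrosine kinase Kit. The sorted populations, all negative for lineage markers and positive for Sca1 and Kit (LSK cells), were long-term hematopoietic stem cells (LT-HSC, CD150 positive and CD48 negative), short-term stem cells (ST-HSC, negative for both) and multipotent progenitors (MPP, CD150 negative and CD48 positive). The design has 6 groups, one per age and population, with 4 libraries each and 24 libraries in all. The labels give 4 mice per age, so libraries of one age probably come from the same mice, but no label links a library number to a mouse. Replicate libraries are taken as separate mice because the labels count the mice that way.

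Per the labels' protocols, first-strand cDNA was made with a reverse transcriptase and not-so-random primers (a primer mix designed to avoid ribosomal RNA), the second strand with Klenow fragment, and libraries with a Nextera XT kit. As described, that chemistry does not mark strand and adds no molecular identifiers. Per the submitters' processing notes, Trim Galore, HISAT2 and featureCounts were used with genome build mm10, and versions, annotation and strand setting are not given in the sources used here. The deposited values are raw integer counts per gene symbol, one table for the series, which the authors had not normalized, judged from the values. The table has 24421 gene lines, and every column matched one sample by its title. Spreadsheet software had turned 27 symbols into dates, 2 of them repeated, and these lines hold at most 0.192% of the counts of a library. The table holds no mitochondrially encoded gene (13 were looked for), so the planned share of counts from those genes, its alternatives and the list of those genes were not computed. Library totals ran from 7307151 to 12946550 counts, with a median of 8652940.

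Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes passing filterByExpr were kept (14205 genes, 99.9% of all counts), TMM factors were computed, and a quasi-likelihood model with robust dispersion was fitted to all 24 libraries with one mean per group, which left 18 residual degrees of freedom. The common dispersion was 0.0454, a biological coefficient of variation of 0.213. Contrasts were aged minus young in each population, the differences of those age effects between populations, and pairs of populations within each age, 12 contrasts in all. Tests are two-sided, adjusted p-values are Benjamini-Hochberg values over the tested genes, and the threshold is 0.05. Levels are CPM, counts scaled to a common library size with TMM factors, as mean ± SD over 4 libraries.

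The groups, tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined, except where a later choice is named. Of 32 gene lists, the 29 with at least 5 tested members were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Adjusted list p-values are Benjamini-Hochberg values over the lists of one contrast. Lists covered the LT-HSC program, genes reported to rise in aged stem cells, platelet and megakaryocyte genes, and lymphoid, myeloid and erythroid priming. Others covered S phase, G2 and M phase, replication histones, ribosomal proteins, immediate early genes, interferon response, MHC class II, p53 targets, senescence-associated secretion, lysosome and autophagy, and chromatin regulators. Metabolic lists covered oxidative phosphorylation, the mitochondrial ribosome, the TCA cycle, glycolysis, mitochondrial dynamics and mitochondrial stress. Marker lists covered B and plasma cells, T and NK cells, granulocytes, monocytes and macrophages, erythroblasts, mast cells with basophils and eosinophils, and endothelial and stromal cells. The list of genes reported to rise in aged stem cells was written from general knowledge of the field, without these counts. Some lists share members, such as Selp, Itgb3 and Vwf in the aged stem cell and platelet lists.

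The rule for naming genes takes, for each age comparison, the sort genes Slamf1, Cd48, Ly6a and Kit, up to 6 higher and 6 lower genes of the largest change, and up to 4 members of smallest p of each list described. The genes of largest change needed an adjusted p under 0.05, a mean of at least 10 CPM over all libraries, and 4 values of one age all above the 4 of the other. Population comparisons take up to 5 genes each way and 3 per list, and differences of age effects take the 6 genes of smallest p. Predicted gene models and pseudogenes are passed over, and some genes that the rule takes are not reported here. Which lists are described for each comparison was chosen after their results were seen, and the rest are given as counts. Where a group has 1 to 3 counts of a gene in all, the ratio is given with its exact 95% counting interval; where it has none, a bound is given against 3 counts over the group. PCR reads without molecular identifiers are not independent molecules, so intervals and bounds cover counting error only.

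Gene positions are from GENCODE release M21 (GRCm38, the same assembly as mm10); 23358 of the 24421 symbols matched it, and 13651 of the 14205 tested. Of the 167 named genes, 18 share exon sequence with another gene of the table, and 4 share over 10% of it, namely Csf1r, Rarb, Rfc2 and Rps25. Without strand, and with the counting rule not given, reads in those stretches cannot be assigned with certainty. The same holds for members of families with near-identical copies, among them replication histones, Ly6c2, Hspa1b and ribosomal protein genes.

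Shares of counts taken by marker lists, ribosomal proteins, histones and the 45S ribosomal RNA gene were compared between ages by exact two-sided permutation of the 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment. Adjustment is over all these shares and populations. A share could pass only if most reached that smallest p, and not passing is no sign of equal ages. Replicate libraries were compared by chi-square on counts; the statistic per degree of freedom was 5.87 to 25.9 over the 36 replicate pairs, so no pair differed by as little as sampling noise. The test was run on simulated data with up to 200 changed genes among 13972. For the age comparisons it recovered 64.9%, 66.3% and 65.7% of genes changed by 1 log2 unit in LT-HSC, ST-HSC and MPP, and 83.7%, 80.8% and 83.8% of those changed by 2 log2 units. The share of false calls was 2.72%, 3.97% and 6.33%. The real data hold more changed genes, and outlying libraries, so these shares may not carry over.

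The other settings tried were RLE scaling, no count filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with sample weights, fits to only the groups compared, libraries thinned to the smallest total, ribosomal RNA and hemoglobin genes left out, a block for age and library number, a 2-fold minimum, and each library left out in turn. Leaving out young LT-HSC library 1 and aged ST-HSC libraries 2 and 3 together was added after the data were seen, as was leaving out each library in turn for the agreement of age effects between populations. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.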

Results

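Transcript levels were measured by bulk RNA-seq in LT-HSC, ST-HSC and MPP sorted from the marrow of young and aged male mice, with 4 libraries in each of 6 groups. Totals of aged LT-HSC libraries 1 to 4 were 8241643, 9881620, 7792983 and 8158805 counts. Those of aged ST-HSC were 12890638, 7760242, 7307151 and 9778462, and those of aged MPP 10705210, 11907421, 10927430 and 10895163. Young LT-HSC libraries held 7938119, 7583212, 9487078 and 12946550 counts, young ST-HSC 7876562, 9031736, 10409244 and 7609208, and young MPP 8784383, 7480426, 8383324 and 8521496. Between 14416 and 16103 genes had a count in a library. The first principal component held 46.6% of the variance. Its group means were -99.2 in aged LT-HSC, -54.7 in young LT-HSC, 3.11 in young ST-HSC, 11.1 in aged ST-HSC, 62.7 in young MPP and 76.8 in aged MPP. The second held 10.7%, and on it the 3 aged groups had lower means than the young groups of the same population.

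Levels are CPM as mean ± SD (n = 4). Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another method is named, and a range of p is over the alternatives run for that result. For each list, the lowest p over the alternatives was at or below camera's preset value, and the highest was the one with an estimated correlation unless another is named. Among named genes past the threshold, values of the ages overlapped for Cd48 and Hist1h2ak in LT-HSC, Cebpe, Csf1r and Lcn2 in ST-HSC, and Calr, Cd79b and Ly6a in MPP.

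**Figure D1:**
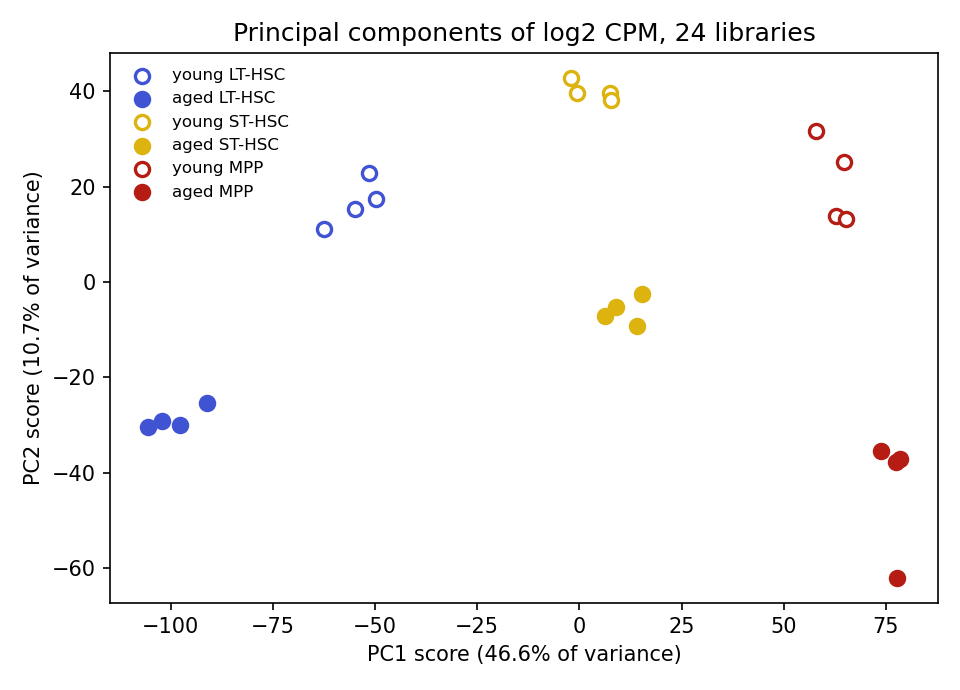
First and second principal components of log2 CPM for the 24 libraries, 1 point per library, with filled points for aged and open points for young mice. The first component (46.6% of the variance) orders the populations and the second (10.7%) separates the ages.

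The first comparison asks what differs between aged and young LT-HSC, the most primitive of the sorted populations. Selp, which encodes the adhesion receptor P-selectin (chromosome 1, 164115264 to 164150026), rose from 9.61 ± 1.14 CPM in young to 453 ± 51.2 CPM in aged LT-HSC, a log2 change of 5.56 (adjusted p = 1.5e-08). The nuclear receptor gene Rorb (chromosome 19, 18930605 to 19111196) rose from 0.764 ± 0.586 (0.505 without library 1) to 61.4 ± 14.2 CPM. The metallothionein gene Mt1 rose from 3.82 ± 1.12 to 105 ± 18.2 CPM. Uhrf1, which keeps DNA methylation through replication (chromosome 17, 56303321 to 56323486), fell from 216 ± 59.6 to 44.8 ± 13.4 CPM, a log2 change of -2.27 (adjusted p = 9.7e-06). In all, 2678 of 14205 genes changed with age in LT-HSC, 1418 higher and 1260 lower, and 807 of them by at least 2-fold.

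Other genes of large change in aged LT-HSC were Tdrd9 (108 ± 14.9 against 2.13 ± 0.348 CPM), Clca3a1 (303 ± 40.7 against 14.3 ± 3.78 CPM) and the peptide transporter gene Slc15a2 (108 ± 87.3 against 4.24 ± 4.84 CPM). Under the rule for naming genes, which asks for a mean of at least 10 CPM over all libraries and no overlap of the ages, the lower genes of largest change besides Clec12a were Siglecg (log2 change -4.44), the linker histone gene Hist1h1b (-3.66), Ubash3a (-2.95), Fam46a (-2.91) and Mthfd2, an enzyme gene of mitochondrial folate metabolism (-2.87, adjusted p = 5.2e-05). Without young LT-HSC library 4 Hist1h1b changed by -2.69, and by -4.74 without aged LT-HSC library 1. Siglecg, Ubash3a and Fam46a changed by -6.09, -3.66 and -3.68 without aged LT-HSC libraries 3, 4 and 3, and Slc15a2 was at 2.02 CPM in young LT-HSC without library 1. Clec12a had 2 counts in all in aged and 67 in young LT-HSC, a ratio with a 95% counting interval of 7.81 to 247. Hist1h1b had adjusted p = 0.074 in a fit to only these groups and 0.17 by limma-voom (range 0.00022 to 0.17). Clec12a had 0.39 by limma-voom, 0.059, 0.060 and 0.056 without aged LT-HSC libraries 1, 3 and 4, 0.099 without young LT-HSC library 1, where it changed by -3.41 in place of -4.65, and 0.092 without the 3 libraries named below (range 0.00069 to 0.39).

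All 34 genes of the list reported to rise in aged stem cells rose in LT-HSC, over all genes and adjusted over the list alone. Their median log2 change was 2.35 (camera, adjusted p = 4.8e-55, and adjusted p = 2.3e-07 with an estimated correlation). Among them were Alcam, an adhesion molecule (351 ± 37.8 against 76.7 ± 14.2 CPM), Enpp5 (212 ± 12.8 against 51.7 ± 5.79 CPM), Sult1a1 (502 ± 53.4 against 117 ± 21.1 CPM) and the BMP receptor gene Bmpr1a (50.3 ± 6.75 against 3.29 ± 2.39 CPM). Of 28 platelet and megakaryocyte genes, 11 rose, 1 fell and 16 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 1.2e-08, and adjusted p = 0.00032 with an estimated correlation). The integrin gene Itgb3 rose from 158 ± 21.9 to 1006 ± 79.3 CPM and Plek from 29.8 ± 16.6 to 196 ± 30.1 CPM. In the LT-HSC program 11 of 30 genes rose and 1 fell, or 13 and 1 adjusted over the list alone (camera, adjusted p = 6e-07, and adjusted p = 0.0058 with an estimated correlation). Nr4a2 was at 335 ± 54.7 against 58.3 ± 12.6 CPM, and Vldlr, Rarb and Pbx3 had log2 changes of 2.53, 1.51 and 1.44.

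Immediate early genes, which respond within minutes to signals or stress, rose for 23 of 34 members and fell for none in aged LT-HSC, or 24 and 0 adjusted over the list alone. Their median log2 change was 1.06 (camera, adjusted p = 2.3e-18, and adjusted p = 0.028 with an estimated correlation). Btg2 rose from 142 ± 28.4 to 537 ± 13.4 CPM, the cytokine signaling inhibitor Socs3 from 7.75 ± 1.49 to 112 ± 16.7 CPM, and Nfkbiz from 264 ± 31.5 to 668 ± 130 CPM. S phase genes fell for 37 of 42 members, or 39 adjusted over the list alone, with a median of -1.22 (camera, adjusted p = 9.9e-34, and adjusted p = 0.046 with an estimated correlation). The replication helicase genes Mcm2 and Mcm6 were at 76.4 ± 7.53 and 123 ± 7.58 CPM in aged against 256 ± 66.3 and 323 ± 67.9 CPM in young LT-HSC. Ung and Rfc2 had log2 changes of -2.38 and -0.81. Replication histones fell for 11 of 42 members, or 18 adjusted over the list alone (camera, adjusted p = 1.7e-07, but adjusted p = 0.53 with an estimated correlation). Among them Hist1h2ac, Hist1h2ad and Hist1h2bg changed by -2.33, -3.61 (-4.34 without aged LT-HSC library 2) and -2.32. A further member, Hist1h2ak, changed by -2.58, but by -1.52 without young LT-HSC library 4 (adjusted p = 0.068, range 0.00025 to 0.068) and -3.33 without aged LT-HSC library 1.

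Of 76 nuclear genes of oxidative phosphorylation, 1 rose and 17 fell in aged LT-HSC, or 1 and 19 adjusted over the list alone. The median log2 change was -0.24 (camera, adjusted p = 3.1e-05, but adjusted p = 0.54 with an estimated correlation). Uqcrc1 of complex III was at 103 ± 2.94 against 140 ± 7.13 CPM, Ndufa4 at 82.0 ± 3.21 against 111 ± 8.62 CPM, and Atp5g1 and Sdhc changed by -0.75 and -0.53. Genes of the mitochondrial ribosome fell for 10 of 76 members, or 6 adjusted over the list alone (camera, adjusted p = 2.7e-05, but adjusted p = 0.47 with an estimated correlation). Among them Mrpl28, Mrpl44, Mrpl45 and Mrpl13 changed by -0.78, -0.73, -0.54 and -0.75. Of 28 chromatin regulators, 5 rose and 13 fell, or 7 and 13 adjusted over the list alone (camera, adjusted p = 0.01, but adjusted p = 0.15 with an estimated correlation). The Polycomb methyltransferase gene Ezh1 rose from 117 ± 15.8 to 208 ± 32.8 CPM, while Satb1 fell from 25.9 ± 1.71 to 10.0 ± 2.75 CPM and Cbx2 changed by -1.19. Of 27 myeloid priming genes, 1 rose and 5 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.0017, but adjusted p = 0.53 with an estimated correlation). Cd34 changed by -1.02, Csf2rb by -1.38, Nkg7 by -1.49 and Csf3r, the G-CSF receptor gene, by 0.53. In young LT-HSC, Mpo was at 681.7 CPM in library 1 and at a mean of 1.97 CPM in the others.

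Of the sort genes, Slamf1, which encodes CD150, was at 72.1 ± 11.7 CPM in aged and 26.2 ± 3.85 CPM in young LT-HSC (adjusted p = 0.011). DESeq2 gave 0.087 (range 2.4e-09 to 0.087). Cd48 was at 0.178 ± 0.241 and 1.25 ± 1.55 CPM (0.017), with adjusted p = 0.080 by limma-voom, 0.051 without aged LT-HSC library 1 and 0.11 without young LT-HSC library 3 (range 0.00028 to 0.11). Its log2 change was -2.77, but -1.54 without young LT-HSC library 3 and -3.87 without aged LT-HSC library 3. Kit was at 1694 ± 82.6 and 1452 ± 103 CPM (0.036). Its adjusted p was 0.084 with no count filter, 0.052 with ribosomal RNA and hemoglobin genes left out, 0.053 in thinned libraries, 0.059 without the 3 libraries, 0.059, 0.11, 0.055 and 0.13 without aged LT-HSC libraries 1 to 4, and 0.062, 0.13 and 0.13 without young LT-HSC libraries 1, 3 and 4 (range 0.0067 to 0.13), with a log2 change of 0.18 to 0.23 where the call was lost against 0.22. Ly6a was at 90.0 ± 18.8 and 58.4 ± 7.19 CPM (0.15) and passed in a fit to only these groups (0.0043, range 0.0043 to 0.32). Counts from T and NK cell markers were 0.0127% ± 0.00242 of the total in aged LT-HSC, 72.0% of it Klrb1c, and 0.00505% ± 0.000773 in young LT-HSC, and the 45S ribosomal RNA gene took 6.46% ± 0.602 and 9.01% ± 1.82. Neither share passed the exact permutation test after adjustment, which no share could do alone. The T and NK cell shares of the ages did not overlap.

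**Figure D2:**
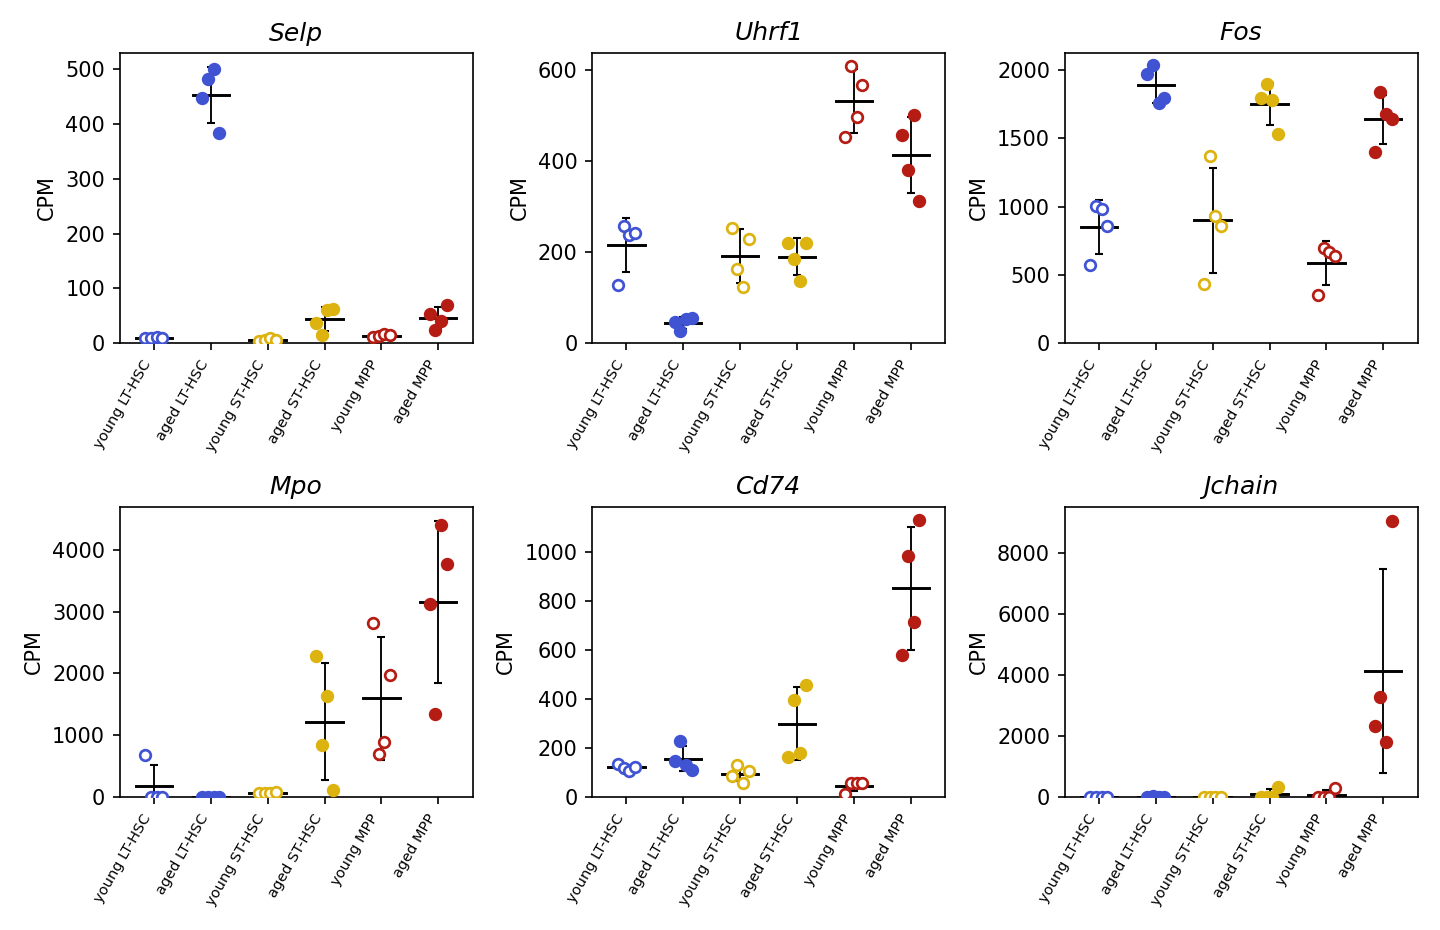
CPM per library of Selp, Uhrf1, Fos, Mpo, Cd74 and Jchain in the 6 groups, with the mean and SD of 4 libraries. Selp is at 453 ± 51.2 CPM in aged and 9.61 ± 1.14 CPM in young LT-HSC.

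In ST-HSC the comparison of ages gave 823 changed genes, 509 higher and 314 lower, 271 of them by at least 2-fold. Bmpr1a (chromosome 14, 34410734 to 34503341) rose from 1.06 ± 0.49 to 28.0 ± 4.95 CPM, a log2 change of 4.71 (adjusted p = 2.1e-08), and the lectin gene Clec1a from 3.30 ± 1.79 to 34.9 ± 8.65 CPM. Genes of neutrophil and monocyte precursors were among those of largest change under the rule for naming genes. Ctsg, a granule protease gene (chromosome 14, 56099881 to 56102574), was at 69.4 ± 64.1 CPM in aged and 0.274 ± 0.276 CPM in young ST-HSC (adjusted p = 0.033). Ly6c2 was at 40.4 ± 30.2 and 0.109 ± 0.09 CPM (0.037), and Ms4a3 at 47.0 ± 41.0 and 0.235 ± 0.355 CPM (0.031). Without aged ST-HSC library 1 Ctsg and Ms4a3 were at 40.2 and 30.1 CPM. Abca13, Rorb and Wwtr1 had 1, 1 and 2 counts in all in young ST-HSC, and their ratios have 95% counting intervals of 204 to 45059, 30.5 to 6828 and 41.9 to 1264. Under the same rule the lower genes of largest change were Plxdc2 (10.3 ± 1.5 against 60.5 ± 9.23 CPM), Slc35d3, Clip3, Mpdz, Igdcc4 and Hmga2, a chromatin protein gene of fetal stem cells (9.89 ± 4.76 against 29.8 ± 8.44 CPM, adjusted p = 0.0014).

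Several of these calls in ST-HSC were lost by another method or with 1 library left out, young or aged, while the folds stayed large. By limma-voom Abca13, Ctsg, Ms4a3 and Ly6c2 had adjusted p = 0.68, 0.47, 0.67 and 0.56, each the highest of its range, against lowest values of 0.0019, 0.00051, 0.00049 and 0.00048. Without aged ST-HSC library 1 they had 0.058, 0.078, 0.066 and 0.067. Ly6c2 had 0.052 and 0.064 without aged ST-HSC libraries 2 and 3, Ctsg and Abca13 0.051 and 0.060 without library 3, and Ms4a3 0.062 in a fit to only these groups. Without young ST-HSC libraries 1 to 4 in turn, Abca13 had 0.10, 0.089, 0.097 and 0.084, Ctsg 0.083, 0.082, 0.098 and 0.085, Ms4a3 0.063, 0.085, 0.090 and 0.081, and Ly6c2 0.091, 0.092, 0.10 and 0.090. Where the call was lost, log2 changes ran from 6.89 to 11.2 for Abca13 (9.58 with all libraries), 7.09 to 8.75 for Ctsg (7.90), 6.88 to 9.13 for Ms4a3 (7.63) and 7.17 to 8.85 for Ly6c2 (8.33). Rorb had 0.054 by limma-voom (range 1.9e-05 to 0.054) and changed by 6.01 without aged ST-HSC library 2, against 6.92. The count of changed genes was 534 in a fit to only these groups, 503 without young ST-HSC library 3 and 543 without young ST-HSC library 2. It was 453 with young LT-HSC library 1 and aged ST-HSC libraries 2 and 3 left out together, a choice made after seeing the data, where Mpdz had 0.13 (range 0.0015 to 0.13).

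Among the genes reported to rise in aged stem cells, 12 of 34 rose and none fell in ST-HSC, or 16 and 0 adjusted over the list alone. The median log2 change was 0.83, or 0.86 without a gene at the floor in both ages (camera, adjusted p = 6.1e-22, and adjusted p = 0.00061 with an estimated correlation). Plscr2 changed by 3.75. Of 28 platelet genes, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera, adjusted p = 0.00014, and adjusted p = 0.0095 with an estimated correlation). Selp was at 43.8 ± 22.4 against 5.79 ± 2.39 CPM, and Itga2b, Plek and F2r had log2 changes of 0.89, 1.27 and 0.56. F2r had adjusted p = 0.19 with the 3 libraries left out (range 0.0031 to 0.19). In the LT-HSC program 3 of 30 genes rose and 4 fell, or 3 and 7 adjusted over the list alone (camera, adjusted p = 0.3). Nr4a2 and Pbx3 changed by 1.85 and 1.08, and Socs2 and Mycn by -3.87 and -0.93. Immediate early genes rose for 17 of 34 members and fell for none, or 24 and 0 adjusted over the list alone, with a median of 1.03 (camera, adjusted p = 8.1e-26, and adjusted p = 0.0076 with an estimated correlation). Socs3 was at 55.6 ± 26.2 against 8.16 ± 1.57 CPM, Btg2 at 389 ± 47.5 against 176 ± 42.5 CPM, and Ier3 changed by 1.13.

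Myeloid priming genes rose for 12 of 27 members and fell for none in aged ST-HSC, or 16 and 0 adjusted over the list alone. Their median log2 change was 1.54 (camera, adjusted p = 3.3e-10, but adjusted p = 0.079 with an estimated correlation). Nkg7 rose from 61.2 ± 8.91 to 174 ± 43.2 CPM and the Fc receptor gene Fcgr3 from 0.37 ± 0.586 (0.0781 without library 4) to 13.4 ± 2.45 CPM. Csf1r, the M-CSF receptor gene, and Cebpe changed by 2.74 and 3.77. By limma-voom Fcgr3, Csf1r and Cebpe had adjusted p = 0.15, 0.18 and 0.28 (lowest values 3e-06, 0.00059 and 0.0045). Csf1r had 0.19 in a fit to only these groups, its highest, 0.085 without aged ST-HSC library 4, where it changed by 1.75, and 0.055 and 0.063 without young ST-HSC libraries 1 and 2. Cebpe had 0.20 without the 3 libraries, and 0.054 and 0.059 without aged ST-HSC libraries 2 and 3, and 0.067, 0.075 and 0.078 without young ST-HSC libraries 2 to 4.

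MHC class II genes, which present antigen, rose for 6 of 7 members in aged ST-HSC, or all 7 adjusted over the list alone (camera, adjusted p = 5.7e-12, and adjusted p = 0.0076 with an estimated correlation). H2-Aa was at 137 ± 63.4 against 36.6 ± 15.3 CPM, H2-Eb1 at 68.6 ± 42.4 against 14.5 ± 5.57 CPM and H2-Ab1 at 91.4 ± 33.2 against 32.4 ± 11.3 CPM, and H2-DMb1 changed by 0.78. In a fit to only these groups H2-Aa, H2-Eb1 and H2-Ab1 had adjusted p = 0.084, 0.089 and 0.079, the highest of their ranges (lowest 4.9e-08, 1.5e-06 and 1.5e-05). H2-DMb1 had 0.053 with the 3 libraries left out (range 0.00049 to 0.053). Markers of monocytes and macrophages, cells that also present antigen, took 0.0756% ± 0.0495 of counts in aged and 0.0304% ± 0.00699 in young ST-HSC.

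Markers of other cells also rose in aged ST-HSC, but not in step with Mpo, which was highest in library 1 and lowest in library 4. Monocyte and macrophage markers took 0.0326%, 0.110%, 0.0338% and 0.126% of counts in aged ST-HSC libraries 1 to 4. Granulocyte markers took 0.0133%, 0.168%, 0.0384% and 0.00190%. Monocyte and macrophage markers rose for 2 of 16 members, or 13 adjusted over the list alone (camera, adjusted p = 7.4e-07, but adjusted p = 0.19 with an estimated correlation). Vcam1 was at 92.1 ± 75.8 against 6.22 ± 4.44 CPM. Granulocyte markers rose for 3 of 10 members, or 5 adjusted over the list alone (camera, adjusted p = 0.0078, but adjusted p = 0.61 with an estimated correlation). Ltb4r1 changed by 2.41, Camp was at 8.64 ± 15.2 against 0.622 ± 0.346 CPM, and Lcn2 had 2 counts in all in young ST-HSC and a ratio of 55.5 to 1672. Without aged ST-HSC library 2 Camp was at 1.01 CPM and Lcn2 at 1.17 CPM in aged ST-HSC, and their log2 changes went from 3.76 to 0.71 and from 7.61 to 4.00. Without aged ST-HSC library 2 the granulocyte list had a median of 0.39 (camera, adjusted p = 0.28). It also missed the threshold without young ST-HSC library 1 (0.075) or 2 (0.090), with a filter of 5 CPM (0.13), by fry (0.098) and with the 3 libraries left out (0.72, median -0.59; range 8.2e-05 to 0.72).

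Among those markers in ST-HSC, Camp had adjusted p = 0.69 without aged ST-HSC library 2, 0.069 and 0.057 without young ST-HSC libraries 2 and 3, and 0.26 by limma-voom (range 0.0092 to 0.76). Lcn2 had 0.16 without aged ST-HSC library 2, 0.099, 0.11, 0.11 and 0.10 without young ST-HSC libraries 1 to 4, 0.47 by limma-voom and 0.060 with no count filter (range 0.010 to 0.93). Vcam1 had 0.079 and 0.082 without aged ST-HSC libraries 2 and 4, and 0.096, 0.10, 0.075 and 0.066 without young ST-HSC libraries 1 to 4. It had 0.15 by limma-voom and 0.098 in a fit to only these groups (range 0.0039 to 0.15). The granulocyte share of counts was 0.0553% ± 0.0765 in aged and 0.00864% ± 0.0161 in young ST-HSC (exact permutation p = 0.171). Without aged ST-HSC library 2 the aged mean was 0.0179%, and without young ST-HSC library 4 the young mean was 0.000611%. No share passed after adjustment, but a share could pass only if most shares reached the smallest possible p. Of the sort genes none passed in ST-HSC by edgeR. Slamf1, Cd48, Ly6a and Kit had log2 changes of -0.11, 0.33, -0.11 and 0.12, with adjusted p from 0.41 to 0.96.

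In MPP, 1391 genes changed with age, 785 higher and 606 lower, 495 of them by at least 2-fold. MHC class II genes rose for all 7 members, over all genes and adjusted over the list alone, with a median log2 change of 2.79 (camera, adjusted p = 6.2e-31, and adjusted p = 0.00014 with an estimated correlation). H2-Aa (chromosome 17, 34282744 to 34287823) rose from 16.6 ± 4.01 to 212 ± 35.4 CPM and H2-Eb1 from 7.79 ± 3.08 to 139 ± 38.3 CPM. Markers of monocytes and macrophages, cells that also present antigen, took 0.0766% ± 0.0457 of counts against 0.0318% ± 0.00633, and members of the B and plasma cell list other than Jchain 0.0312% ± 0.0186 against 0.0135% ± 0.00586. Jchain, which joins secreted antibody chains (chromosome 5, 88519809 to 88527891), was at 4117 ± 3354 CPM in aged and 71.8 ± 142 CPM in young MPP (adjusted p = 0.036). Without library 4 of each group the means were 2469 and 0.927 CPM. The calcium channel genes Cacna1h and Cacna1e rose from 0.452 ± 0.904 to 98.1 ± 40.9 CPM and from 1.2 ± 1.42 to 74.8 ± 33.7 CPM, with all young counts of Cacna1h in library 4 and 0.683 CPM for Cacna1e without library 1, and Bmpr1a from 0.276 ± 0.122 to 19.2 ± 3.54 CPM. Hmga2 fell from 61.7 ± 8.02 to 11.8 ± 4.74 CPM and the zinc finger gene Plag1 from 28.8 ± 4.21 to 3.57 ± 2.03 CPM (adjusted p = 6.3e-06 and 7.4e-07). Clip3, Mpdz, Plxdc2 and Fstl1 changed by -3.13, -2.81 (-3.43 without aged MPP library 4), -2.51 and -2.41.

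Clec9a and Evc had 3 and 2 counts in all in young MPP, and their ratios have 95% counting intervals of 37.2 to 533 and 32.2 to 972. Cacna1h had adjusted p = 0.070 by DESeq2 (range 0.00029 to 0.070) and Clip3 0.065 by limma-voom (range 7.5e-05 to 0.065). Jchain had 0.14 in a fit to only these groups, 0.050 and 0.085 without aged MPP libraries 2 and 4, and 0.081, 0.095 and 0.086 without young MPP libraries 1 to 3 (range 0.0011 to 0.14). The count of changed genes was 914 without aged MPP library 4.

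Immediate early genes rose for 23 of 34 members in aged MPP and 1, the heat shock gene Hspa1b, fell, or 28 and 1 adjusted over the list alone. The median log2 change was 1.17 (camera, adjusted p = 1.8e-26, and adjusted p = 0.0073 with an estimated correlation). Socs3 was at 60.2 ± 12.1 against 10.3 ± 4.80 CPM, Fosb, which encodes a subunit of the AP-1 transcription factor, at 534 ± 73.8 against 147 ± 44.7 CPM, and Btg2 and Ier3 changed by 1.06 and 1.16. In the LT-HSC program 2 of 30 genes rose and 10 fell, or 2 and 13 adjusted over the list alone, with a median of -0.34 (camera, adjusted p = 8.8e-08, and adjusted p = 0.0057 with an estimated correlation). Hlf fell from 665 ± 83.2 to 364 ± 49.8 CPM, and Mycn and Mecom changed by -1.35 and -0.59. Among the 34 genes reported to rise in aged stem cells, 8 rose and 1 fell, or 8 and 2 adjusted over the list alone (camera, adjusted p = 0.0059, but adjusted p = 0.32 with an estimated correlation and 0.063 with no count filter). The median was 0.12, and -0.01 without aged MPP library 1. Clec1a, Itgb3 and Rhob changed by 4.71, 1.61 and 1.02.

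B and plasma cell markers rose for 6 of 14 members in aged MPP, or 8 adjusted over the list alone. The median log2 change was 1.11 (camera, adjusted p = 0.063, and adjusted p = 0.59 with an estimated correlation). The list passed with no count filter (0.044), in a fit to only these groups (0.00021), without aged MPP library 1 (0.024) or 3 (0.015) and without young MPP library 3 (0.029). Fcrla was at 30.4 ± 13.2 against 0.272 ± 0.318 CPM and Mzb1, a chaperone gene of antibody secretion, at 72.4 ± 56.7 against 3.77 ± 2.75 CPM (46.7 without aged and 2.47 without young MPP libraries 4 and 3). Without young MPP library 4 Fcrla was at 0.162 CPM in young MPP and Ms4a1 changed by 5.29. Ms4a1, which encodes CD20, and Cd79b changed by 4.37 and 0.84. Ms4a1 had adjusted p = 0.40 by DESeq2 (range 8.2e-05 to 0.40) and Cd79b 0.064 in a fit to only these groups (range 0.0014 to 0.064). The list took 0.420% ± 0.325 of counts in aged and 0.0205% ± 0.0136 in young MPP (exact permutation p = 0.0286, adjusted p = 0.107). Jchain made up 92.6% of the aged share. Without aged MPP library 4 the aged mean of the whole list was 0.261%.

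Myeloid priming genes rose for 4 of 27 members in aged MPP, or 5 adjusted over the list alone (camera, adjusted p = 3.4e-05, but adjusted p = 0.32 with an estimated correlation). Irf8, a regulator of monocytes and dendritic cells, was at 188 ± 32.7 against 56.1 ± 27.0 CPM, and Calr, Csf2rb and Spi1 changed by 0.53, 0.62 and 0.49. Calr had adjusted p = 0.071 in a fit to only these groups (range 0.0002 to 0.071). Spi1 had 0.057, 0.054 and 0.10 without aged MPP libraries 1, 2 and 4 and 0.15 without young MPP library 2 (range 0.0090 to 0.15). Monocyte and macrophage markers rose for 2 of 16 members, or 10 adjusted over the list alone (camera, adjusted p = 3.3e-05, but adjusted p = 0.32 with an estimated correlation). Ctss was at 83.0 ± 34.8 against 16.3 ± 2.72 CPM and Ccr2 at 20.0 ± 3.77 against 2.43 ± 4.07 CPM (0.402 without young MPP library 1). Ccr2 had 0.068 with no count filter, 0.098 by DESeq2 and 0.14 in a fit to only these groups. It had 0.072, 0.068, 0.075 and 0.070 without aged MPP libraries 1 to 4, and 0.082 and 0.10 without young MPP libraries 3 and 4 (range 2.5e-06 to 0.14).

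Ribosomal protein genes rose for 12 of 81 members in aged MPP, or 25 adjusted over the list alone. The median log2 change was 0.34 (camera, adjusted p = 1.1e-12, but adjusted p = 0.37 with an estimated correlation). Rps25 was at 766 ± 88.4 against 534 ± 42.4 CPM, and Rps24, Rpl10 and Rpl19 changed by 0.41, 0.45 and 0.35. Of 40 interferon response genes, 4 rose and 8 fell, or 5 and 10 adjusted over the list alone (camera, adjusted p = 0.15, and 0.016 without aged MPP library 1). The immunoproteasome genes Psmb8 and Psmb9 changed by 0.52 and 0.48, Isg20 by 0.78 and Parp14 by -0.37. Rpl19 had adjusted p = 0.060 without young MPP library 2 (range 0.0021 to 0.060), and Psmb9 0.055 without aged MPP library 2 and 0.066 without young MPP library 2 (range 0.0029 to 0.066).

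Of the sort genes in MPP, Ly6a, which encodes Sca1, rose from 30.2 ± 9.22 to 77.2 ± 38.0 CPM (adjusted p = 0.0071). A fit to only these groups gave 0.12 (range 6.7e-05 to 0.12). Cd48, Slamf1 and Kit had changes of 0.44, 0.11 and -0.09 (0.38, 0.96 and 0.53). Cd48 passed by limma-voom (0.0032) and in a fit to only these groups (0.0061, range 0.0032 to 0.55).

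**Figure D3:**
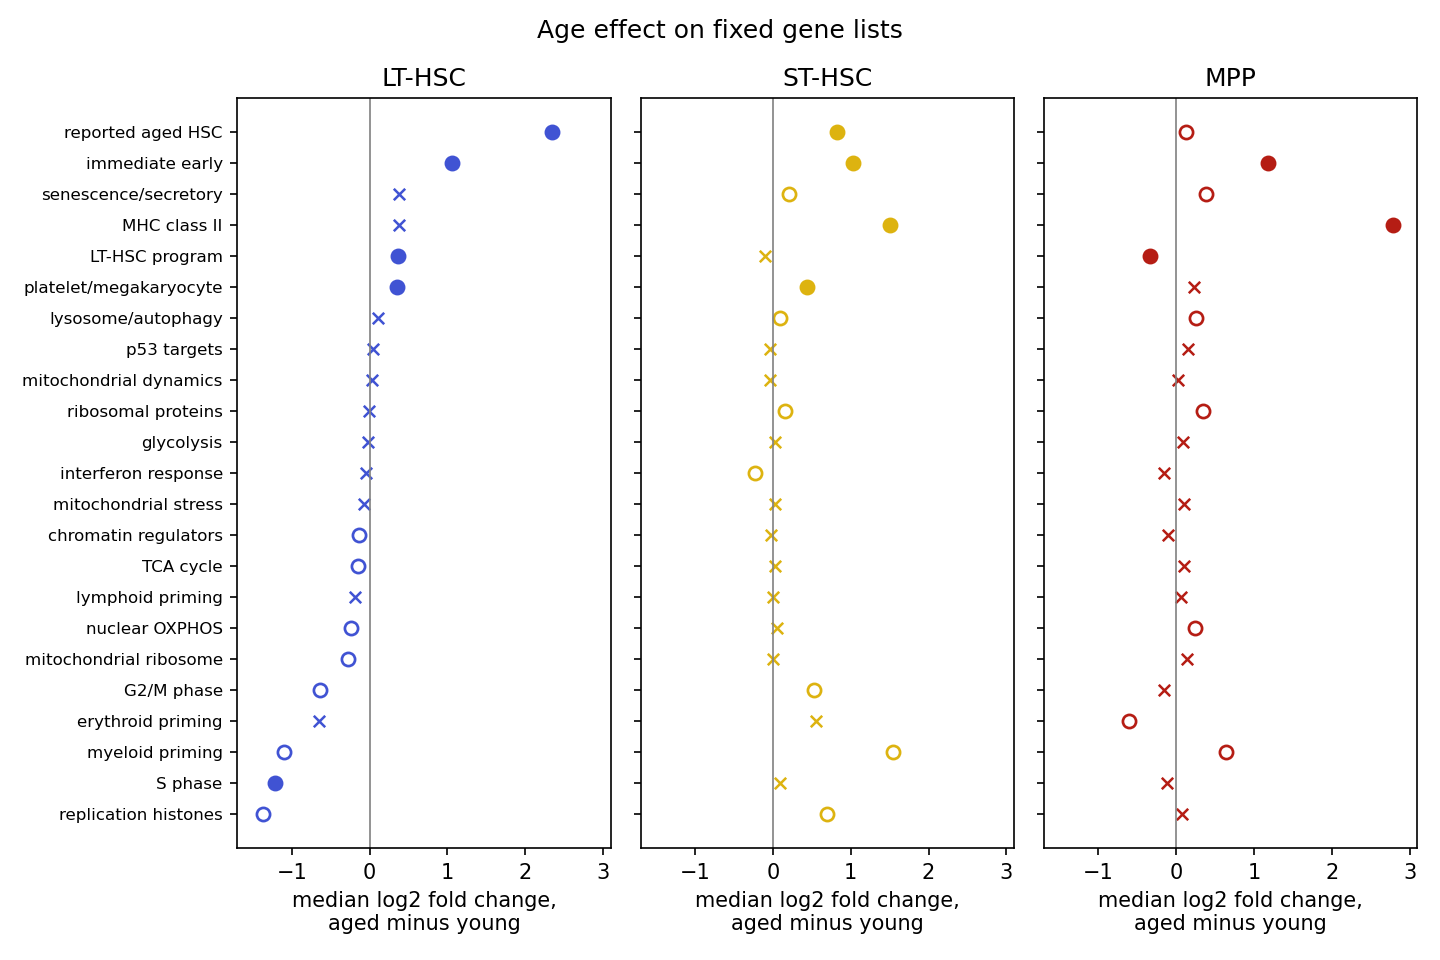
Median log2 fold change, aged minus young, of each fixed gene list in the 3 populations. Filled circles passed camera's threshold of 0.05 with the preset and with an estimated correlation, open circles with the preset only, and crosses with neither.

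Differences of the age effects were tested directly. Between LT-HSC and ST-HSC the age effect differed for 575 genes, 235 with a higher and 340 with a lower change in LT-HSC. Gpr183, an oxysterol receptor gene of immune cell guidance (chromosome 14, 121952551 to 121965195), was at 183 ± 35.4 CPM in aged against 16.7 ± 3.83 CPM in young LT-HSC. In ST-HSC it was at 16.3 ± 1.48 against 17.1 ± 1.32 CPM, a difference of log2 changes of 3.52 (adjusted p = 1.7e-10). Alcam and Enpp5 differed by 2.09 and 1.73, and the nucleoside transporter gene Slc28a2 and the potassium channel gene Kcna3 by -1.87 and -1.85. Between LT-HSC and MPP the effect differed for 1411 genes, 717 higher and 694 lower. Gpr183, Alcam and St3gal1 were at 3.19, 2.24 and 1.29 and Slc28a2 at -2.06.

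Between ST-HSC and MPP the age effect differed for 66 genes, 26 higher and 40 lower in ST-HSC. Xbp1, a regulator of secretory cells (chromosome 11, 5520659 to 5525893), was at 195 ± 66.5 against 57.0 ± 7.37 CPM in MPP and 69.2 ± 4.49 against 64.3 ± 6.78 CPM in ST-HSC, a difference of -1.67. Txndc5, which folds secreted proteins, was at 517 ± 209 against 104 ± 11.9 CPM in MPP and 83.7 ± 16.4 against 80.4 ± 6.16 CPM in ST-HSC (-2.26). Tmem154, Trib1 and Ell2 differed by -1.97, -1.97 and -1.90. Members of the B and plasma cell list other than Jchain took 0.0312% ± 0.0186 of counts in aged MPP and 0.00327% ± 0.00148 in aged ST-HSC. DESeq2 gave 944 genes between LT-HSC and ST-HSC and 180 between ST-HSC and MPP. Between ST-HSC and MPP a fit to only these groups gave 25, 13 higher and 12 lower, and the one without the 3 libraries named above 24, 14 higher and 10 lower, so the larger direction turned. Between LT-HSC and ST-HSC there were 377 without young LT-HSC library 3 and 897 without the 3 libraries.

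Among lists, the LT-HSC program had a higher age effect in LT-HSC than in ST-HSC for 7 of 30 members, or 12 adjusted over the list alone (camera, adjusted p = 2.8e-10, and adjusted p = 0.002 with an estimated correlation). Against MPP it was higher for 18, or 20 higher and 2 lower adjusted over the list alone (adjusted p = 9.3e-17, and adjusted p = 8.9e-05 with an estimated correlation). In ST-HSC against MPP it was higher for 3 and lower for 1, or 11 and 2 adjusted over the list alone (adjusted p = 2.7e-06, and adjusted p = 0.012 with an estimated correlation). Genes reported to rise in aged stem cells had a higher effect in LT-HSC than in ST-HSC for 9 of 34, or 16 higher and 1 lower adjusted over the list alone (adjusted p = 2.2e-14, and adjusted p = 0.0024 with an estimated correlation). Against MPP they were higher for 17 and lower for 1, or 19 and 2 adjusted over the list alone (adjusted p = 5.2e-22, and adjusted p = 0.00025 with an estimated correlation). Platelet genes had a higher effect in LT-HSC than in ST-HSC for 7 of 28, or 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.0027, and adjusted p = 0.035 with an estimated correlation). S phase genes had a lower effect in LT-HSC than in ST-HSC for 22 of 42, or 37 adjusted over the list alone (adjusted p = 9.2e-43, and adjusted p = 0.022 with an estimated correlation). Against MPP they were lower for 22, or 34 adjusted over the list alone (adjusted p = 2e-23, but adjusted p = 0.10 with an estimated correlation).

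Myeloid priming genes had a lower age effect in LT-HSC than in ST-HSC for 12 of 27, or 1 higher and 19 lower adjusted over the list alone (camera, adjusted p = 1.3e-16, and adjusted p = 0.022 with an estimated correlation). MHC class II genes had a lower effect in LT-HSC than in MPP for 6 of 7, or 7 adjusted over the list alone (adjusted p = 1e-13, and adjusted p = 0.0038 with an estimated correlation). Between ST-HSC and MPP 6 of the 7 were lower adjusted over the list alone (adjusted p = 1.1e-11, and adjusted p = 0.012 with an estimated correlation). Over all genes the member of smallest p, Cd74, had a difference of -2.57 (adjusted p = 0.0667). Immediate early genes did not pass as a list between LT-HSC and ST-HSC (camera, adjusted p = 0.23, range 0.037 to 0.79), LT-HSC and MPP (0.86, range 0.32 to 0.99) or ST-HSC and MPP (0.23, range 0.025 to 0.96). The first passed without aged LT-HSC library 3 (0.037) or young ST-HSC library 4 (0.045), and the last without aged MPP library 3 (0.035) or young ST-HSC library 4 (0.025). For the first, camera's direction was up and the median difference -0.01.

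Age effects were also compared across genes, which are not independent replicates. Pearson's r of the log2 changes was 0.167 between LT-HSC and ST-HSC, 0.154 between LT-HSC and MPP and 0.434 between ST-HSC and MPP, and Spearman's rho 0.266, 0.175 and 0.443. The age comparisons share no library, but libraries of one age probably come from the same 4 mice, so differences between those animals can enter all 3 comparisons. Sharing between independent lists is for that reason not the value expected without an effect of age. Genes higher in both populations numbered 267, 226 and 216 for these pairs, where independent lists would share 50.8, 78.4 and 28.1. Genes lower in both numbered 122, 115 and 141, against 27.9, 53.8 and 13.4. In all 3 populations 127 genes rose and 57 fell, where independent lists would share 2.81 and 1.19.

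Populations were compared within each age. In young mice, 1780 genes differed between LT-HSC and ST-HSC (964 higher in LT-HSC), 5287 between LT-HSC and MPP (2683 higher) and 2929 between ST-HSC and MPP (1495 higher). Flt3, a cytokine receptor gene of multipotent and lymphoid progenitors (chromosome 5, 147330741 to 147400489), was at 28.7 ± 2.12 CPM in LT-HSC, 391 ± 49.0 CPM in ST-HSC and 485 ± 26.4 CPM in MPP. Mecom, a transcription factor gene of stem cells (chromosome 3, 29951296 to 30548008), was at 342 ± 14.9, 191 ± 5.79 and 78.2 ± 9.79 CPM. Dntt, the lymphoid DNA polymerase gene, had no count in young LT-HSC and was at least 400-fold higher in ST-HSC (31.6 ± 17.1 CPM) and at least 3381-fold higher in MPP (259 ± 55.6 CPM). Sdpr, named Cavin2 in the annotation, was at 42.9 ± 9.44 CPM in LT-HSC and 0.244 ± 0.41 CPM in ST-HSC (0.0417 without library 3), and Cd34 at 174 ± 48.6, 667 ± 49.8 and 829 ± 8.17 CPM in the order given. Ctsg was at 0.274 ± 0.276 CPM in ST-HSC (0.147 without library 2) and 92.9 ± 82.2 CPM in MPP, with adjusted p = 0.26 by limma-voom (range 5.5e-05 to 0.26).

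Of 30 LT-HSC program genes in young mice, 20 were higher and 3 lower in LT-HSC than in ST-HSC, 27 higher and 1 lower than in MPP, and 23 higher in ST-HSC than in MPP. Adjusted over the list alone these were 22 and 4, 27 and 1, and 26 and 0 (adjusted p = 2.2e-05, 2.1e-07 and 8.3e-07 with an estimated correlation). Lymphoid priming genes were lower for 14 of 25 members in LT-HSC than in ST-HSC and for 21 than in MPP, or 17 and 22 adjusted over the list alone (adjusted p = 8.4e-06 and 9.6e-06 with an estimated correlation). Satb1 was at 25.9 ± 1.71, 179 ± 29.9 and 392 ± 28.8 CPM in LT-HSC, ST-HSC and MPP. In ST-HSC against MPP lymphoid genes were higher for 2 and lower for 15, or 2 and 17 adjusted over the list alone (adjusted p = 0.0027 with an estimated correlation). Myeloid priming genes were lower for 8 of 27 members in LT-HSC than in ST-HSC, with the same count adjusted over the list alone. The list's median and mean log2 difference were 0.33 and 0.75 while camera's direction was down (adjusted p = 0.00098, but adjusted p = 0.56 with an estimated correlation). Without young LT-HSC library 1, where Mpo was at 681.7 CPM, the median was -0.42. Against MPP, 13 were lower in LT-HSC and 14 in ST-HSC, or 16 and 19 adjusted over the list alone (adjusted p = 0.098 and 0.11 with an estimated correlation).

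G2 and M phase genes in young mice were lower for 51 of 52 members in LT-HSC than in MPP and for 47 in ST-HSC than in MPP, or 51 and 52 adjusted over the list alone (adjusted p = 0.29 and 0.099 with an estimated correlation). Between LT-HSC and ST-HSC 1 was higher and 1 lower (camera, adjusted p = 0.21). That list passed in a fit to only these groups (0.050), without young ST-HSC libraries 2 (0.042) and 3 (0.0062) and without young LT-HSC library 4 (0.041; range 0.0062 to 0.88). Ckap5, a spindle protein gene, was at 131 ± 15.2, 150 ± 29.3 and 276 ± 15.7 CPM. Oxidative phosphorylation genes were lower for 25 of 76 members in LT-HSC and in ST-HSC than in MPP, or 25 and 29 adjusted over the list alone (adjusted p = 0.60 and 0.28 with an estimated correlation). Between LT-HSC and ST-HSC 1 was lower, and none adjusted over the list alone (camera, adjusted p = 0.86). That gene was Ndufa4, at 111 ± 8.62, 139 ± 12.1 and 267 ± 13.5 CPM. Its difference between LT-HSC and ST-HSC had adjusted p = 0.084 and 0.070 without young ST-HSC libraries 1 and 4, and 0.072 and 0.10 without young LT-HSC libraries 2 and 4 (range 0.0056 to 0.10).

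In aged mice, 4582 genes differed between LT-HSC and ST-HSC (2301 higher in LT-HSC), 8068 between LT-HSC and MPP (4016 higher) and 4244 between ST-HSC and MPP (2196 higher). Clu, which encodes the chaperone clusterin (chromosome 14, 65968483 to 65981547), was at 129 ± 24.1 CPM in LT-HSC and 0.37 ± 0.507 CPM in ST-HSC (0.123 without library 1). Mpo, the gene of the granule enzyme myeloperoxidase (chromosome 11, 87793581 to 87804413), was at 0.515 ± 0.196 CPM in LT-HSC, 1217 ± 948 CPM in ST-HSC and 3155 ± 1319 CPM in MPP. Ctsg had no count in aged LT-HSC and was at least 880-fold higher in ST-HSC and at least 3866-fold higher in MPP. Matn4 had none in aged MPP and was at least 1364-fold higher in LT-HSC (96.6 ± 15.1 CPM). Jchain was at 82.8 ± 164 CPM in ST-HSC and 4117 ± 3354 CPM in MPP (adjusted p = 0.017), or 1.03 and 2469 CPM without library 4 of each, and Irf4 at 2.71 ± 1.82 and 178 ± 113 CPM. By limma-voom LT-HSC against ST-HSC and against MPP gave adjusted p = 0.29 and 0.14 for Mpo (ranges 4.2e-17 to 0.29 and 5.4e-22 to 0.14) and 0.33 and 0.14 for Ctsg (ranges 3.2e-37 to 0.33 and 1.4e-44 to 0.14). A fit to only these groups gave 0.055 for Ctsg in LT-HSC against ST-HSC and 0.11 for Jchain. Without the 3 libraries Jchain had 0.13 (range 0.00044 to 0.13), and 2698 genes differed between ST-HSC and MPP.

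Of the LT-HSC program genes in aged mice, 25 were higher and 2 lower in LT-HSC than in ST-HSC, with the same counts adjusted over the list alone. Against MPP 28 were higher and 1 lower in LT-HSC, and 26 higher and 2 lower in ST-HSC (adjusted p = 7.2e-06, 7e-07 and 4.2e-07 with an estimated correlation in that order). Lymphoid priming genes were lower for 16 of 25 members in LT-HSC than in ST-HSC, or 17 adjusted over the list alone, for 23 than in MPP, and for 17 in ST-HSC than in MPP (adjusted p = 6.4e-05, 0.00026 and 0.0058 with an estimated correlation). Myeloid priming genes were lower for 22 of 27 members in LT-HSC than in ST-HSC, or 25 adjusted over the list alone (camera, adjusted p = 8.1e-15, and adjusted p = 0.023 with an estimated correlation). They were lower for 25 in LT-HSC than in MPP and for 6 in ST-HSC than in MPP (adjusted p = 0.064 and 0.36 with an estimated correlation). Nkg7 was at 6.72 ± 2.22, 174 ± 43.2 and 245 ± 52.6 CPM. Beside these, granulocyte markers were lower in LT-HSC than in ST-HSC for 8 of 10 members and monocyte and macrophage markers for 10 of 16, and B and plasma cell markers were lower in ST-HSC than in MPP for 13 of 14.

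G2 and M phase genes in aged mice were lower for 40 of 52 members in LT-HSC than in ST-HSC, for 50 than in MPP and for 23 in ST-HSC than in MPP (adjusted p = 0.48, 0.28 and 0.39 with an estimated correlation). Adjusted over the list alone the first and last were 45 and 29. Oxidative phosphorylation genes were lower for 22, 65 and 52 of 76 in that order, or 22, 66 and 61 adjusted over the list alone (adjusted p = 0.55, 0.28 and 0.20 with an estimated correlation). Ndufa4 was at 82.0 ± 3.21, 136 ± 16.6 and 279 ± 40.2 CPM.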

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

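The shares of the way toward MPP, the joint variation of myeloid genes and the comparison of library numbers are tests chosen only after the result they bear on was seen, as was the minimum mean of 10 CPM for genes searched for outlying libraries.

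Plasma cell genes were higher in all 4 aged MPP libraries, with Jchain at 2324, 3289, 1794 and 9061 CPM and Irf4 at 117.6, 323.7, 64.5 and 204.6 CPM. In a further plasma cell list, written before its values were seen except for Ell2, which was already named, 11 of 12 members rose (10 of 11 without Ell2), among them Slamf7 (4.39) and Tnfrsf17 (5.98). Fkbp11 did not pass (0.97, adjusted p = 0.312), and 7 of the 12 were at 10 CPM or more in young MPP too. In a plasmacytoid dendritic cell list 2 of the 4 tested members rose, Tcf4 (0.33) and Ly6d (3.42), which met the share set beforehand, but 5 of its 9 genes were too low to test (Siglech at 5.45 ± 8.67 CPM) and a minimum on coverage, added after that was seen, leaves it undecided. Plasma cells or their RNA may account for the pattern although the sort for lineage-negative, Sca1-positive and Kit-positive cells would remove most of them, and expression by MPP of aged mice was not tested and stays open.

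Myeloid genes were higher in aged ST-HSC, with Mpo at 2287, 842.1, 1631 and 105.3 CPM against 55.04, 54.49, 68.4 and 77.81 CPM in young libraries. If cells of the MPP gate were the source, other genes of young MPP would follow. The 12 myeloid genes that rose moved 60.8% of the way from young ST-HSC to aged MPP (quartiles 33.3% and 72.3%). Choosing genes that rose raises that share. Another 56 MPP genes moved 21.8% (14.1% and 27.1%), Cd48 3.71% and Dntt 5.97%. The 21.8% lies between the bounds set for and against MPP cells, on an uneven comparison. Over the 4 aged ST-HSC libraries the first component held 94.0% of the variance of those 12 genes, against a median of 65.2% and a highest of 98.1% for 1000 random lists (16 as high). That met the share set for joint variation. A first component also takes in opposite changes, so it does not show that the whole program varied together. Csf1r, among the 12, was at 85.83 CPM in library 4, where Mpo was lowest, against a mean of 17.2 CPM in the others. Whether cells with myeloid RNA came through the MPP gate is left undecided by these shares, and whether they belong to the ST-HSC of aged mice was not tested and stays open.

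Immediate early genes were higher with age in each population, with median log2 changes of 1.06, 1.03 and 1.17 in LT-HSC, ST-HSC and MPP. Transcript length and GC content are excluded as the cause, since the highest median of 1000 matched lists in any population was 0.226 and none reached the list's own. Handling or the day of sorting may contribute. Libraries of the same number shared the list's level with an exact permutation p of 0.139 in young and 0.0451 in aged mice (576 arrangements), and since no label gives a day and each age could have had its own, handling cannot be told apart from age. An effect of age itself was not tested apart from it and stays open.

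A library far from the other 3 of its group was found in 12 of 84 groups of library measures and in 16 of 202 groups of gene values, where chance gives about 5% of groups. Among the measures, aged MPP library 2 had 15825 genes with a count and young ST-HSC library 4 a TMM factor of 1.06. Replication histones took 0.0206% of counts in aged ST-HSC library 3. Aged ST-HSC library 4 had 0.0384% from B and plasma cell markers and 0.00910% from T and NK cell markers. Granulocyte markers took 0.00391% in young LT-HSC library 1 and 0.0327% in young ST-HSC library 4. Monocyte and macrophage markers took 0.0266% in aged LT-HSC library 2 and 0.145% in aged MPP library 4. Mast cell, basophil and eosinophil markers took 0.000133% in aged LT-HSC library 1 and 0.0509% in young MPP library 3, and endothelial and stromal markers 0.0696% in young MPP library 1.

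Among genes, young LT-HSC library 1 stood apart for Rarb (29.06 CPM), Uhrf1 (127.5 CPM) and Uqcrc1 (129.1 CPM), library 3 for Itgb3 (125.2 CPM) and library 4 for Hist1h1b (64.59 CPM). In young ST-HSC library 3 H2-Ab1 was at 15.54 CPM, and in aged ST-HSC library 2 Lcn2 was at 51.6 CPM. In young MPP, Btg2 and Irf8 were at 157.5 and 96.48 CPM in library 1, Rps25 and Spi1 at 470.2 and 52.15 CPM in library 2, and Jchain at 284.4 CPM in library 4. In aged MPP, Mycn was at 29.51 CPM in library 2, Mecom and Socs3 at 61.53 and 42.24 CPM in library 3, and Itgb3 at 93.26 CPM in library 4.

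The age effect differed between LT-HSC and ST-HSC for 575 genes by the test of the difference, among them Gpr183 (3.52), Alcam (2.09), Slc28a2 (-1.87), Kcna3 (-1.85) and Enpp5 (1.73). Of 100 splits drawn that keep the group sizes, 3 gave as many, the real one included, and the highest other gave 1230. Between LT-HSC and MPP it differed for 1411 genes, among them Gpr183 (3.19), Alcam (2.24), Slc28a2 (-2.06) and St3gal1 (1.29), and 1 of 100 splits gave as many, the real one, with 892 in the highest other. Between ST-HSC and MPP it differed for 66 genes, among them Tmem154 (-1.97), Txndc5 (-2.26), Trib1 (-1.97), Xbp1 (-1.67) and Ell2 (-1.90), and 3 of 100 splits gave as many, with 198 in the highest other. These splits mix the ages within each population, so its own age effect becomes spread between replicates, and they bear on no age effect at all rather than on an equal one, which leaves open whether chance is excluded for the 3 differences. The other splits of high count keep one population's ages whole and mix the other's, so the first's own age effect enters the difference. The split with 1230 genes swaps all 4 ages of LT-HSC, the one with 198 those of MPP, and both mix ST-HSC.

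For the age comparisons, 1 of the 35 splits of 8 libraries, the real one, gave as many genes. The real and highest other counts were 2678 and 50 in LT-HSC, 823 and 2 in ST-HSC, and 1391 and 9 in MPP. The same held for populations. In young mice the counts were 1780 and 1 for LT-HSC against ST-HSC, 5287 and 4 for LT-HSC against MPP, and 2929 and 3 for ST-HSC against MPP. In aged mice they were 4582 and 141, 8068 and 1, and 4244 and 32 in that order. For age, chance is excluded at the 0.05 level, unadjusted over counts, with 1 of 35 the smallest share possible. How low mixed splits lie adds nothing, as they turn the real difference into replicate spread. Populations of one age probably share mice, which the splits ignore, so chance stays open there.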

How the results depend on the processing

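Leaving out the 3 libraries named above, or each library for the correlation of age effects, was chosen only after the data were seen. So was the permutation of library numbers. No call reversed in the direction of its test, but medians of lists with a call changed sign. That of granulocyte genes went from 3.22 to -0.59 for age in ST-HSC and from -4.01 to 1.02 for the difference between LT-HSC and ST-HSC without the 3 libraries, where both lost the call. In MPP that of genes reported to rise in aged stem cells went from 0.12 to -0.01 without aged MPP library 1. Between young LT-HSC and ST-HSC that of myeloid genes went from 0.33 to -0.03 in a fit to only these groups, -0.42 without young LT-HSC library 1 and -0.43 without the 3 libraries. The named genes give 310 values of a gene in a comparison, 302 of them called, and the described lists 96, with 81 called. Over the alternatives 5296 of 5462 values of called genes kept the call and 166 lost it, and 3 others gained one. For lists 1590 of 1672 kept it, 82 lost it and 21 gained one. All 297 alternative values of shares of counts moved by less than the spread between replicates or kept the main outcome, and no share had a call to lose. Of other values, mostly counts of genes, 342 stayed within 1.5 times the value reported and 27 did not. Limma-voom lost 30 of 302 calls of genes, fits to only the groups compared 16 of 288, DESeq2 4 of 301, leaving out the 3 libraries 12 of 206 and single libraries 94 of 2560, while RLE scaling lost 0 of 302. With an estimated correlation 44 of 81 called lists lost the call, and over all lists tested 54 passed in place of 172.

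A minimum of 2-fold lowers counts by construction. It left 807, 271 and 495 genes for age in LT-HSC, ST-HSC and MPP, and 304 and 628 for the differences of LT-HSC from ST-HSC and from MPP. For LT-HSC against ST-HSC, LT-HSC against MPP and ST-HSC against MPP it left 783, 2151 and 936 in young and 1943, 3793 and 1280 in aged mice. For age in ST-HSC, 534 genes passed in a fit to only those groups and 453 without the 3 libraries. The difference between LT-HSC and ST-HSC gave 944 by DESeq2 and 897 without the 3 libraries, and that between ST-HSC and MPP 180 by DESeq2, 25 in a fit to only those groups and 24 without the 3 libraries. Without them 2698 genes differed between aged ST-HSC and MPP. Fewer libraries enter some of these fits. Otherwise the cause was not tested.

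With each library left out in turn, the counts ran from 2035 to 2603 for age in LT-HSC, 503 to 713 in ST-HSC and 914 to 1358 in MPP. For the differences of age effects they ran from 377 to 822 between LT-HSC and ST-HSC, 1007 to 1616 between LT-HSC and MPP and 46 to 93 between ST-HSC and MPP. For populations in the same order they were 1428 to 1575, 4606 to 5022 and 2263 to 2876 in young mice, and 4041 to 4616, 7638 to 7772 and 3455 to 4070 in aged mice. Among these, 503 came without young ST-HSC library 3, 914 without aged MPP library 4 and 377 without young LT-HSC library 3. Over genes called in either population, the correlations of age effects were 0.317, 0.217 and 0.513, against 0.167, 0.154 and 0.434 over all genes. The share of genes with the higher change in ST-HSC among those that differed from MPP was 39.4%, but 52.0% in the fit to only those groups and 58.3% without the 3 libraries.

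A block for age and library number did not move any count by over 1.5 times. With it 2671, 818 and 1397 genes passed for age in LT-HSC, ST-HSC and MPP, and 590, 1499 and 70 for the differences of age effects. Of 302 calls of named genes 299 were kept with the block and 3 lost, namely Camp (adjusted p = 0.12) and Lcn2 (0.11) for age in ST-HSC and Clec9a (0.050) between young ST-HSC and MPP, and of 81 calls of lists 80 were kept and 1, the myeloid genes of the difference between ST-HSC and MPP, had 0.055. The numbers did not meet the bar set for pairing, every pair over 0.1. Deviations from the group mean had a median correlation of 0.036 for the same number within an age, over 0.1 in 4 of 24 pairs, and -0.012 for different numbers, and in 19 of 48 comparisons of a library with another population it correlated best with its own number, where chance gives 12. By exact permutation of the numbers (576 arrangements) the mean correlation of the same number had p = 0.101 in young and 0.00521 in aged mice, a hint from the data, not the design, that libraries of aged mice with the same number share variation. A comparison with splits by mouse had been planned only for numbers that meet the bar of 0.1 and was not run, so what shared animals add to the agreement of age effects between populations stays open. The alternatives for mitochondrial genes were not run because the table used holds none.

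Depth limits genes near the floor. The smallest library held 7307151 counts, and genes with 1 or 2 counts in a young group, such as Abca13 and Lcn2, have wide counting intervals.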

Other observations

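Whether the projections on the axis from MPP to ST-HSC differ was a test chosen only after the result was seen, as were the genes named here, which lie outside the rule for naming genes.

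Cdkn1a, which encodes the cell cycle inhibitor p21, was higher with age in each population, from 6.26 to 42.4 CPM in LT-HSC (log2 change 2.75, adjusted p = 7.7e-08), with 2.18 in ST-HSC and 1.84 in MPP. Of 24 p53 targets 4, 2 and 4 rose in LT-HSC, ST-HSC and MPP (camera, adjusted p = 0.14, 0.68 and 0.15), or 5, 2 and 4 adjusted over the list alone. Other members were Trp53inp1 (1.52) and Pmaip1 (3.04) in MPP. Of 10 genes of senescence-associated secretion 3 rose in MPP, among them Cxcl2 (3.09), 2 in ST-HSC, and 1 rose and 1 fell in LT-HSC (camera, adjusted p = 0.0017, 0.011 and 0.42, but adjusted p = 0.10, 0.17 and 0.66 with an estimated correlation), or 4, 3, and 1 and 1 adjusted over the list alone. Of 34 lysosome and autophagy genes 8 rose and 1, Npc1, fell in LT-HSC, with Lamp2 at 0.68, and 7 rose in MPP, with Wipi1 at 1.34 and Ctsz at 0.80, against 1 in ST-HSC (camera, adjusted p = 0.14, 0.00063 and 0.027, but 0.32 in MPP and 0.65 in ST-HSC with an estimated correlation). Adjusted over the list alone 8 rose in MPP and the other counts were the same. Lymphoid priming genes included Flt3, which fell in LT-HSC (-1.17), where 2 of 25 rose and 4 fell, or 2 and 5 adjusted over the list alone (camera, adjusted p = 0.064).

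Of 19 glycolysis genes 3 rose and 5 fell in LT-HSC, with Hk2 at 1.10, Ldha at 0.49 and Pgk1 at -0.52, and 3 fell in ST-HSC, Ldhb (-0.85), Slc2a1 (-0.73) and Aldoc (-1.44), while 2 rose and 2 fell in MPP (camera, adjusted p = 0.85, 0.31 and 0.80). Adjusted over the list alone these were 4 and 6, 3 and 4, and 2 and 2. Of 21 TCA cycle genes 3 fell in LT-HSC, among them Idh2 (-0.54) and Sdhb (-0.40; camera, adjusted p = 0.041, but adjusted p = 0.53 with an estimated correlation), and 1 rose in ST-HSC. Among genes of mitochondrial dynamics 1 of 35, Tomm20 (0.35), rose in MPP, and among those of mitochondrial stress 1 of 20, Chac1 (6.58), rose in MPP (camera, adjusted p = 0.74 and 0.22). Of 20 erythroid genes 2 fell in MPP, Car2 (-0.60) and Tal1 (-0.50; camera, adjusted p = 0.014, but adjusted p = 0.65 with an estimated correlation). Of 40 interferon response genes 3 fell in ST-HSC, Stat2 (-0.53), Irf9 (-0.43) and Mx2 (-1.51), or 4 adjusted over the list alone (camera, adjusted p = 0.0006, but adjusted p = 0.48 with an estimated correlation). G2 and M phase genes fell for 7 of 52 members in LT-HSC and 1, Gas2l3, rose, or 5 and 1 adjusted over the list alone (camera, adjusted p = 1.6e-07, but adjusted p = 0.54 with an estimated correlation).

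Of markers of other cells, endothelial and stromal markers rose for 2 of 14, Stab2 (2.89) and Fabp4 (3.92), and fell for 2, Emcn (-1.71) and Tie1 (-0.84), in aged MPP, or 2 and 4 adjusted over the list alone (camera, adjusted p = 0.22). T and NK cell markers rose for 1 of 7 in MPP, Klrb1c, and 1 in LT-HSC (camera, adjusted p = 0.21 and 0.90). Mast cell, basophil and eosinophil markers, with 4 tested members too few for the list test, rose for 1, Prg2, in MPP. Adjusted over the list alone 2 rose in MPP and all 4 in ST-HSC, where the list took 0.00142% of counts in aged and 0.000384% in young libraries. Erythroblast markers had median log2 changes of -0.81, -0.02 and 0.01 in LT-HSC, ST-HSC and MPP (camera, adjusted p = 0.15, 0.36 and 0.65). No share of counts from marker lists passed after adjustment. The smallest exact permutation p was 0.0286 (adjusted p = 0.107), the floor of the test, so this shows no lack of difference. The sign of median, mean and test differed for lymphoid, p53, glycolysis and mitochondrial ribosome genes in ST-HSC and for glycolysis genes in MPP, all with camera's adjusted p above the threshold.

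Among the 57 genes that fell in all 3 populations was Nnt, the nicotinamide nucleotide transhydrogenase gene (chromosome 13, 119335448 to 119408997), at 83.8, 88.7 and 92.1 CPM in aged against 155, 158 and 181 CPM in young LT-HSC, ST-HSC and MPP (log2 changes -0.88, -0.83 and -0.97). As background, the C57BL/6J substrain carries a deletion within Nnt, the labels name no substrain, and counts per exon were not analysed here. Others that fell were Oxct1 (-1.76, -0.91 and -0.59) and Wdfy1 (-0.47, -0.52 and -0.88). Bmpr1a (chromosome 14, 34410734 to 34503341, minus strand) rose in all 3, and the gene that ends 6446 bp from its end, Mmrn2 (34375465 to 34404287, plus strand), had no count in any young group and 1.05 ± 0.545, 1.83 ± 2.37 and 0.804 ± 0.228 CPM in aged LT-HSC, ST-HSC and MPP. The counts are not known to use strand, so the gene of origin of those reads is uncertain.

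A hypothesis from the first principal component was that aged LT-HSC may lie farther from MPP than young LT-HSC. On the axis set by young MPP, at 0, and young ST-HSC, at 81.6 ± 6.80, aged LT-HSC lay at 121 ± 6.82 and young LT-HSC at 98.5 ± 1.76 (exact permutation p = 0.0286, the smallest that 70 arrangements can give). Aged ST-HSC lay at 59.2 ± 2.60, closer to MPP. Young ST-HSC and young MPP define the axis, so values of ST-HSC of the 2 ages are not on equal terms, and the test was made on the data that raised it.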
